A study of Mus musculus with 7 samples.

How the data were processed

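RNA from 7 samples of mouse cells was measured on Illumina bead arrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I digestion, and labelled as biotinylated cRNA. The samples were grouped by cell type and treatment as the labels give them: MEF (2 arrays), MEF-iN (2), Hep-iN (1), hepatocyte (1) and cortical neuron (1).

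The values used were the deposited series table, whose unit is intensity on a linear scale as the authors made it. The scaling or background step behind it is not given in the sources used here. The median of the deposited intensity was 55.3 and 43.6 on the MEF arrays, 46.4 on the array labelled cortical neuron, 46.1 and 50.9 on the MEF-iN arrays, 34.4 on the Hep-iN array and 41.9 on the hepatocyte array. The Hep-iN column held 631 values below 0. A second deposited table, of values before normalization, was not used here, because its 14 columns of sample values (7 of signal) carry names that match no sample label. No columns were identical.

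The design written before the data were examined called for limma's neqc with detection p-values, which the table used does not hold. In its place, each array's background was taken as the mode of its values, with the SD of the values below it. Values were corrected by limma's normexp with these parameters, given an offset of 16, put on the log2 scale and quantile normalized. A probe counted as above background on an array when it exceeded the mode by more than 5 SD. These steps were chosen after the values were seen. A normexp fit by saddle point was tried first, placed the background near the lowest values, and is kept as an alternative. Of 25697 probes, 23978 had 1 gene symbol and 1719 had none. Symbols came from the platform's annotation, and 23962 probes were updated through Entrez ID to the RefSeq annotation of GRCm38. There were 15211 probes above background on at least 1 array, and the brightest probe of each gene was kept, giving 10306 genes. For 2811 genes several probes were kept before this step, and for 21 of them probes went 2-fold in opposite directions in MEF-iN against MEF. Probes above background numbered 10884 and 12020 on the MEF arrays, 11869 on the array labelled cortical neuron, 11096 and 11011 on the MEF-iN arrays, 11382 on the Hep-iN array and 10987 on the hepatocyte array. Between replicates, 95% of genes differed by less than 0.95 (MEF) and 0.62 (MEF-iN) on the log2 scale, and 406 and 77 genes differed by 2-fold or more.

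MEF-iN and MEF were compared by limma 3.58.1 in R 4.3.3, with a linear model of 5 groups over 7 arrays and empirical Bayes with an intensity trend. The fit had 2 residual degrees of freedom and a median of 4.57 prior ones. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Comparisons with a lone array were described by size, with a pooled limma fit as an alternative. Genes there were counted when they differed by 4-fold or more on the log2 scale of group means and were above background on every array of the brighter group. The difference between the conversions was tested as an interaction in the same limma fit, which assumes that the lone arrays vary like the replicated ones. A gene counts as above background on an array where any of its probes is, while its level comes from the kept probe, which can be below. Where a gene was not above background on any array of the dimmer group, its fold is given as a bound. The bound sets the bright group's mean against the dim group's mean of a floor, which on each array is the lowest signal among probes above background, or the probe's own signal if higher. The same bound is given for a named gene whose kept probe was above background on some arrays of the dimmer group only. The floor is taken over probes, so a gene's kept probe can lie under it while another probe of the gene is above background. No fold is given where both groups were below background.

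Before the data were examined, 32 gene lists were fixed from general knowledge, covering neuronal, glial, mesenchymal, hepatic, blood and cell state genes. Of 840 entries, 557 were measured, and 1 list had no measured member. In MEF-iN against MEF, lists were tested by limma's camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Elsewhere a list's median was placed among 10000 random lists of the same size, matched on expression in 20 bins. Lists of genes chosen on arrays of the series were measured only in contrasts that use none of those arrays.

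Genes were named by a rule fixed at the same time. For MEF-iN against MEF it takes the 8 largest increases and the 8 largest decreases past the threshold whose arrays do not overlap and that are above background on both arrays of the higher group. For the other comparisons it takes the 8 largest each way that meet the size rule. Names of loci and clones were skipped. For each list described, up to 4 members above background with the largest differences may be named. Ascl1, Pou3f2, Myt1l, Mapt, Tubb3, Map2, Alb, Snap25 and Col1a1 were always looked up. Genes named outside this rule are said to be so.

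The limma fit was tested on simulated data, with differences added to 100 genes each. It recovered 11% of 100 genes at a log2 difference of 1 and 90% of 100 genes at 2. It called 0 of the unchanged among 9751 genes. Far fewer genes were changed there than the 5557 of 10306 that passed in the data. The simulated noise was drawn value by value and not gene by gene. These rates need not hold for the real comparison. Alternatives changed 1 choice at a time: the background correction, its offset, the normalization, the filter on detection, the handling of several probes, the test, the thresholds and the arrays used. Alternatives added after the values were seen were the saddle point fit, the authors' scaling alone, detection at 3 SD, and all results without the array labelled cortical neuron. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.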

Results

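Gene expression was measured on 7 Illumina bead arrays of mouse cells, to follow what happens when fibroblasts or liver cells are turned into neurons by 3 transcription factors. The factors were Ascl1, Brn2 (gene symbol Pou3f2) and Myt1l, delivered by lentivirus. There were 5 groups of cells on a mixed C57BL/6;129S background. Mouse embryonic fibroblasts (MEF), uninfected and at passage 3, had 2 arrays. Neurons induced from MEF (MEF-iN), collected 13 days after infection and sorted for GFP, had 2 arrays. Neurons induced from hepatocytes (Hep-iN), 13 days after infection and sorted for GFP and tdTomato together, had 1 array. Hepatocytes had 1 array, taken from tdTomato-positive cells on day 12 of culture. Postnatal cortical neurons also had 1 array, taken from GFP-positive cells on day 13 of culture. GFP was expressed from the Tau (Mapt) locus, which marks neurons. The tdTomato reporter was switched on by Cre under the albumin promoter, which marks cells that are or were hepatocytes. The series' design text speaks of 21 days where the sample labels say 13, and the sample labels are followed here. Between 10884 and 12020 of the 25697 probes were above background on each array, and 10306 genes were compared. All levels are normalized log2 intensities, and the number of arrays limits their precision.

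Replicate arrays resembled each other more than they resembled arrays of any other group. Across genes, the MEF arrays correlated at r = 0.976 and the MEF-iN arrays at r = 0.991. The MEF arrays differed by 4-fold or more for 24 genes and the MEF-iN arrays for 1 gene. Genes are not independent replicates, so these values describe the arrays only. The Hep-iN array was closest to the hepatocyte array (r = 0.872), then to the MEF-iN arrays (r = 0.851 and 0.840). The array labelled cortical neuron correlated with the MEF-iN arrays (r = 0.788 and 0.780) about as closely as with the MEF arrays (r = 0.785 and 0.783).

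The delivered factors were measured first, since they check the labels of the infected cells. Pou3f2 stood at 9.65 ± 0.01 (SD, n = 2) in MEF-iN and 8.67 on the Hep-iN array, against 5.04 ± 0.66 (SD, n = 2) in MEF, where it was above background on 1 of the 2 arrays. It was 5.37, not above background, on the hepatocyte array. Myt1l stood at 8.57 ± 0.10 (SD, n = 2) in MEF-iN and 8.56 on the Hep-iN array, and was not above background on the other 4 arrays. Whether these probes read the delivered copies, the cells' own genes or both is not known here. Ascl1 had no named probe, and the probes of Tubb3, Alb and Snap25 were not above background on any array, so these genes check nothing. Mapt, the locus used for sorting, was 9.85 ± 0.00 (SD, n = 2) in MEF-iN, 8.07 on the Hep-iN array and 6.67 on the array labelled cortical neuron. It was not above background in MEF or hepatocytes. Levels that follow the sorting locus are no finding. The array labelled cortical neuron showed strong glial genes, and its pan-neuronal and synaptic genes were lower than in MEF-iN (below). Its GABAergic genes were the highest of the 7 arrays (median level 6.41, next 5.21 on the Hep-iN array), and its glutamatergic genes (6.66) were near those of MEF-iN (6.94 and 6.86). The glial genes go against its label, and it is called by its label throughout.

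In MEF-iN compared with MEF, genes of the synaptic vesicle were among those that rose the furthest, and genes of the extracellular matrix, the contractile cytoskeleton and cell division fell. This comparison asks what differs between sorted MEF-iN and uninfected MEF, and it is the only one with 2 arrays on each side. The factors, the infection, the sort for GFP and the time after infection cannot be told apart here. Syt4, a vesicle protein of the synaptotagmin family, rose at least 104-fold (limma adjusted p = 1.12e-05), and the vesicle proteins Syn1 and Syp rose at least 98.1-fold and 84.3-fold at the same adjusted p. Also among the 8 largest increases were the transporter-like vesicle protein Svop (at least 118-fold), the Notch-related receptor Dner (at least 118-fold), the neuropeptide gene Nts (at least 111-fold), Sult4a1 (at least 102-fold) and Fam155a (at least 51.7-fold). None of these 8 was above background on either MEF array. The largest decrease was in Timp1, a secreted inhibitor of matrix proteases, which was at least 224-fold lower in MEF-iN (limma adjusted p = 1.32e-05) and above background on 1 of the 2 MEF-iN arrays. Actg2, a smooth muscle actin, was at least 74.1-fold lower in MEF-iN, the gap junction gene Gjb2 at least 54.8-fold, the matrix protein Thbs1 at least 59.6-fold, Lrrc15 at least 24.7-fold and the mitotic activator Cdc20 at least 39.6-fold. Tenascin C (Tnc) fell by 5.85 ± 0.18 (SE) on the log2 scale, and the water channel Aqp1, above background on 1 of the 2 MEF-iN arrays, was at least 50.1-fold lower. In limma, the adjusted p of these 7 decreases lay between 1.12e-05 and 0.000134.

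All 35 measured pan-neuronal genes passed the test in MEF-iN against MEF, with 34 up and 1 down, and the list's median log2 difference was 4.07, or 3.55 with genes below background in MEF at their bound. Its largest members were the granins Scg3 (at least 57.8-fold) and Scg2 (at least 46.2-fold), Rtn1 (at least 65.9-fold, above background on 1 MEF array) and Nsg2 (at least 30.0-fold). The member that fell was the adhesion molecule Ncam1 (-0.67, limma adjusted p = 0.0330), named here after its value was seen. All 23 synaptic vesicle and release genes rose (median 3.85, or 3.51 at the bounds), among them Sv2a (at least 56.2-fold). Of 21 neurogenic transcription factors and Notch ligands, 13 rose and 8 did not pass (median 1.24, or 0.98 at the bounds). These included Dll3 (at least 14.3-fold), St18 (at least 12.6-fold), Myt1 (at least 10.9-fold) and Insm1 (at least 7.88-fold). Of 9 voltage-gated channel genes 7 rose, led by the potassium channel Kcnc1 (at least 5.32-fold), 1 fell and 1 did not pass (median 1.34, or 0.48 at the bounds). Among 12 glutamatergic genes 6 rose, including the AMPA receptor subunit Gria2 (at least 65.3-fold) and the kinase Camk2b (at least 26.7-fold, above background on 1 MEF array), 1 fell and 5 did not pass. Among 8 GABAergic genes 3 rose, including Dlx2 (at least 2.16-fold) and Gabrb1 (at least 2.32-fold), each above background on 1 MEF array, and 5 did not pass. Map2, a dendritic protein, rose by 1.67 ± 0.19 (SE, limma adjusted p = 0.000466). That call was lost when the gene's detected probes were averaged (0.23, limma adjusted p = 0.347), since its probes differed.

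Of 38 fibroblast and matrix genes 34 fell, 1 rose and 3 did not pass (median -2.33, or -2.31 at the bounds). Lox, which crosslinks collagen, fell by 4.42, and Col1a1 fell by 1.64 ± 0.38 (SE, limma adjusted p = 0.00998). Col1a1 missed the threshold without MEF-iN replicate 2 (limma adjusted p = 0.0610). The member that rose was the proteoglycan Dcn (1.68, limma adjusted p = 0.00306), singled out after its value was seen. All 11 smooth muscle and contractile genes fell (median -3.14), including Tagln (at least 25.4-fold lower) and Acta2 (-4.53). Of 16 mesenchymal transcription factors 9 fell, among them Foxc2 (at least 12.2-fold lower), Prrx1 (-4.07) and Twist2 (-3.80), 1 rose and 6 did not pass (median -1.16). Of 37 proliferation genes 36 fell and 1 did not pass (median -3.32, or -3.07 at the bounds), including the centromeric histone Cenpa (-5.45), the spindle protein Prc1 (-5.43) and Tk1 (at least 14.7-fold lower). Of 13 neural progenitor genes 6 fell, including Vim (-4.02), Notch1 (-2.41) and the Notch target Hes1 (-2.33), and 7 did not pass. Vim is also a member of the fibroblast and matrix list. Zic1, Nr2e1 and Lhx2 of the progenitor list, named here outside the rule, were not above background in MEF. A fall of these genes could not be seen. Of 27 interferon response genes 11 fell, including Ifitm3 (-3.87) and Bst2 (at least 4.25-fold lower, above background on 1 of the 2 MEF-iN arrays), 2 rose and 14 did not pass. Of 24 Hox genes 12 rose, including Hoxd4 (at least 6.42-fold), Hoxb7 (at least 4.52-fold) and Hoxb5 (at least 5.26-fold), the latter 2 above background on 1 MEF array, 2 fell and 10 did not pass. The MEF arrays stood apart here, with a median Hox level of 6.85 on replicate 1 and 5.21 on replicate 2, against 6.82 and 6.90 in MEF-iN. Of 15 macrophage genes none passed the limma test, adjusted over all genes or over the list alone.

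In limma, 5557 of 10306 genes passed an adjusted p of 0.05 in MEF-iN against MEF (2906 up, 2651 down), where 6118 had an unadjusted p under 0.05. Nothing says that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Camera with a preset correlation, adjusted over 31 lists, called 11 lists, and none of these calls held with an estimated correlation. Its adjusted p was 2.63e-16 for proliferation, 1.81e-15 for pan-neuronal, 9.32e-12 for both the synaptic and the fibroblast lists, 1.51e-07 for smooth muscle and 0.00109 for the neurogenic list. It was 0.00959 for mesenchymal factors, 0.00982 for neural progenitor, 0.0322 for voltage-gated channels and 0.0448 for both the interferon list and the delivered factors, and missed the threshold for Hox genes (0.0529; 0.0118 without MEF replicate 1 and 0.281 without MEF replicate 2). The adjusted p = 0.163 with an estimated correlation was the lowest, shared by the pan-neuronal, synaptic and proliferation lists. It was 0.398 for the smooth muscle and neurogenic lists and 0.490 for the fibroblast list. The estimated correlation rests on 2 residual degrees of freedom, so missing the threshold with it does not speak against a list. The preset correlation is assumed and not measured. With it, the calls of voltage-gated channels, interferon response and the delivered factors were each lost when either MEF array was left out. Adjusted over the list alone, the counts stayed at 34 up and 1 down for pan-neuronal, 23 up for synaptic, 13 up for neurogenic and 36 down for proliferation genes. For the fibroblast list, 1 was up and 35 were down when adjusted over the list alone. The count of passing genes was 3494 without MEF-iN replicate 2, and 1963 in limma's test against a 2-fold change.

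**Figure D1:**
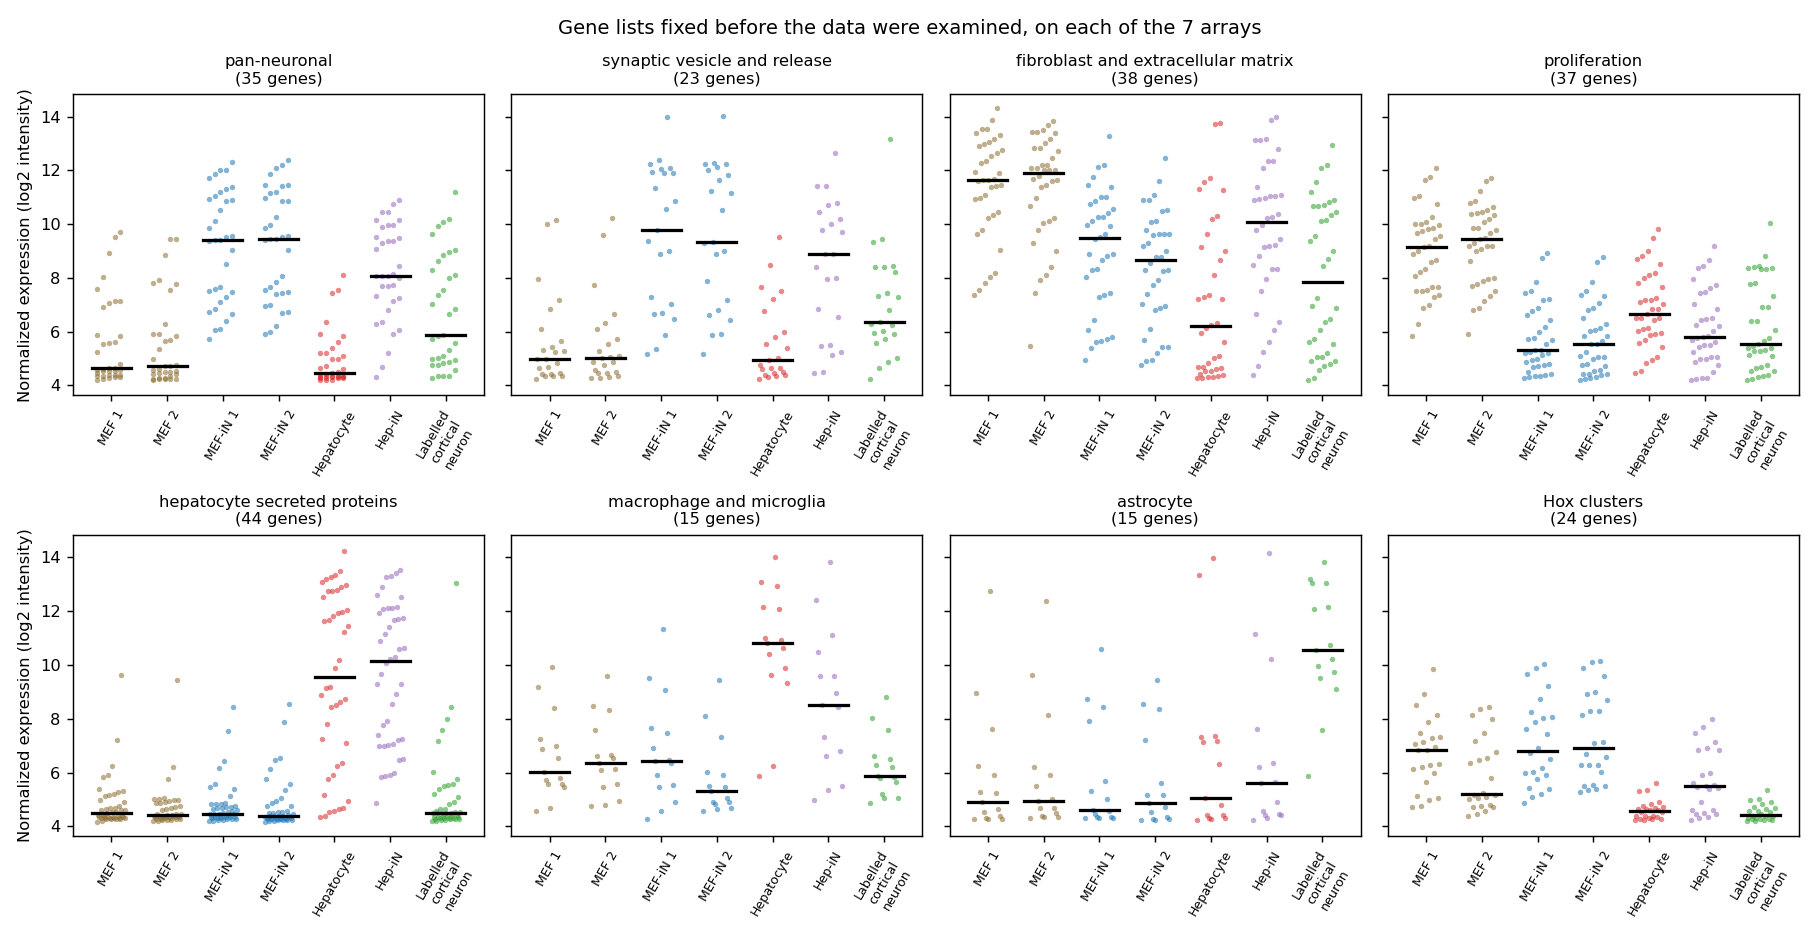
Normalized log2 intensity (vertical axis) of the measured members of 8 fixed gene lists on each of the 7 arrays, with a point for each gene and a bar at the list's median. The pan-neuronal list is highest on the MEF-iN arrays and next on the Hep-iN array, the astrocyte list is highest on the array labelled cortical neuron, and the hepatocyte secreted protein list is high on the hepatocyte and Hep-iN arrays.

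In Hep-iN compared with hepatocytes, neuronal and matrix genes were higher and macrophage genes were lower, while hepatocyte genes showed no common direction. This comparison asks what differs between Hep-iN and hepatocytes, where the factors, the infection and the sort for GFP again cannot be told apart. The comparison sets 1 array against 1, so there is no replicate check and no p-value, and genes are named by size alone. The neuropeptide gene Gal was at least 139-fold higher on the Hep-iN array, Dner at least 82.7-fold, the glucagon gene Gcg at least 62.4-fold, Syt4 at least 55.3-fold, the secretory chaperone Scg5 at least 52.5-fold and the amino acid transporter Slc38a5 at least 38.2-fold. None of these was above background on the hepatocyte array. The matrix genes Dcn (6.96 on the log2 scale) and Col3a1 (at least 42.5-fold) completed the 8 largest increases. The 8 largest decreases were led by the haemoglobin scavenger receptor Cd163 (at least 118-fold lower in Hep-iN). Fcna (at least 49.0-fold), the scavenger receptor Marco (at least 43.6-fold), the transporter Slco2b1 (at least 21.1-fold) and the lectin Clec10a (at least 13.2-fold) followed. Cd163, Marco and Clec10a are genes of macrophages. The others were the sulfotransferase Sult1a1 (-4.60), Fgfbp1 (at least 12.8-fold lower) and the cystine transporter Slc7a11 (-4.34).

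Of 35 pan-neuronal genes, 28 were at least 4-fold higher on the Hep-iN array and none was 4-fold lower. The median log2 difference was 3.44, or 2.48 over the 32 members with a value or a bound. Scg3 (at least 28.3-fold), Chgb (at least 28.6-fold), Scg2 (at least 20.2-fold) and Resp18 (at least 20.1-fold) led the list. Of 23 synaptic genes 15 were 4-fold higher (median 3.35), including Syp (5.61) and Syn1 (at least 28.3-fold). Map2 was at least 22.9-fold higher by its brightest probe. The neurogenic genes Dll3 (at least 17.2-fold) and Insm1 (at least 12.8-fold) were higher too, in a list of 21 with a median of 0.91. Of 38 fibroblast and matrix genes 22 were 4-fold higher and none 4-fold lower (median 2.97), among them the proteoglycan Bgn (5.92) and Col1a1 (at least 11.5-fold). Lists of other cells that make or border matrix were also higher on the Hep-iN array. The median was 1.33 for 9 hepatic stellate genes (1.24 at the bounds), with Reln at least 15.0-fold and Cygb at least 2.36-fold higher, and 0.79 for 16 mesenchymal transcription factors (0.58 at the bounds), with Twist1 at least 2.23-fold higher. It was 0.76 for 8 endothelial genes, with Emcn at least 3.82-fold higher and Stab1 lower (-2.47). Reln was also at least 4-fold higher in MEF-iN than in MEF, so its rise is not particular to the hepatocyte conversion. Interferon response genes had a median of 0.67, with Isg15 at 3.25 and Oasl2 at 3.19. ER stress genes had a median of -0.997, with the transcription factor Atf3 at -4.14. Proliferation genes had a median of -0.74, with none of 37 as much as 4-fold apart. Each of these medians except the endothelial lay beyond the central 99% of 10000 random lists of the same size and expression level, which describes these arrays only.

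Hepatocyte lists did not move as a block. Of 44 genes for proteins that hepatocytes secrete, 9 were 4-fold higher on the Hep-iN array and 4 were 4-fold lower, with a median of 0.01 (-0.08 at the bounds) that turned to -0.24 under median scaling and -0.05 under the authors' scaling alone. Plasminogen (Plg, at least 4.36-fold), Orm1 (2.99) and Apoa2 (2.97) were higher, and Serpina1e was lower (-2.41). Of 29 hepatocyte metabolism genes 5 were 4-fold higher and 3 were 4-fold lower. Their median was -0.57 and their mean 0.02, which differ in sign. The bile acid enzyme Cyp7b1 was at least 3.11-fold higher and Cyp27a1 was lower (-2.55). Of 18 hepatocyte transcription factors, the median was -0.52, with Creb3l3 at -2.54 and Cebpa at least 2.87-fold lower. Macrophage genes, which the hepatocyte array carried at high levels, were lower in Hep-iN. Of 15, 6 were 4-fold lower and none was 4-fold higher (median -1.42), including the complement genes C1qa (-3.78), C1qc (-3.74) and C1qb (-3.12). In total 560 genes were at least 4-fold higher and 166 at least 4-fold lower on the Hep-iN array. With genes below background at their bound, 388 and 137 remained past 4-fold. An offset of 50 in the background correction, which shrinks differences of dim genes, gave 437 genes in place of 726, and the pooled limma fit, in which lone arrays are assumed to vary like the replicated ones, called 1566.

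The conversions of fibroblasts and hepatocytes shared their largest neuronal increases. Across 10306 genes, the log2 differences of MEF-iN against MEF and of Hep-iN against hepatocytes correlated at Pearson's r = 0.433 and Spearman's rho = 0.436. The comparisons share no array, and genes are not independent replicates. There were 292 genes at least 4-fold higher in both conversions, where independent lists would share 43.8, and 21 at least 4-fold lower in both, where 11.1 would be shared. Another 65 genes were 4-fold apart in opposite directions. Dner, Syt4, Nts, Svop and Scg5 were among the genes 4-fold higher in both. The difference between the conversions was set up as an interaction in the pooled limma fit, which also takes in the difference between the starting cells. The hepatocyte conversion has 1 array on each side, so its spread is assumed to equal that of the MEF and MEF-iN arrays, and no value here measures it. Under that assumption 2401 genes passed, 1211 with a higher and 1190 with a lower value in the hepatocyte conversion. The count depended on single arrays: it was 4322 without MEF replicate 1, 3940 without MEF replicate 2, 1303 without MEF-iN replicate 1 and 1138 without MEF-iN replicate 2. Syt4 (-0.84, limma adjusted p = 0.128), Dner (-0.28, limma adjusted p = 0.564), Pou3f2 (-1.31, limma adjusted p = 0.146) and Myt1l (0.00, limma adjusted p = 0.999) did not pass, which does not show that their changes were equal. Under the same assumption Col1a1 (6.10, limma adjusted p = 0.00237), Map2 (3.08, limma adjusted p = 0.00227) and Mapt (-1.74, limma adjusted p = 0.0182) passed. None of these 3 was above background in hepatocytes, nor Mapt in MEF, so the sizes depend on the floor of the signal. The size for Map2 also rests on its brightest probe, since its probes differed in MEF-iN against MEF.

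**Figure D2:**
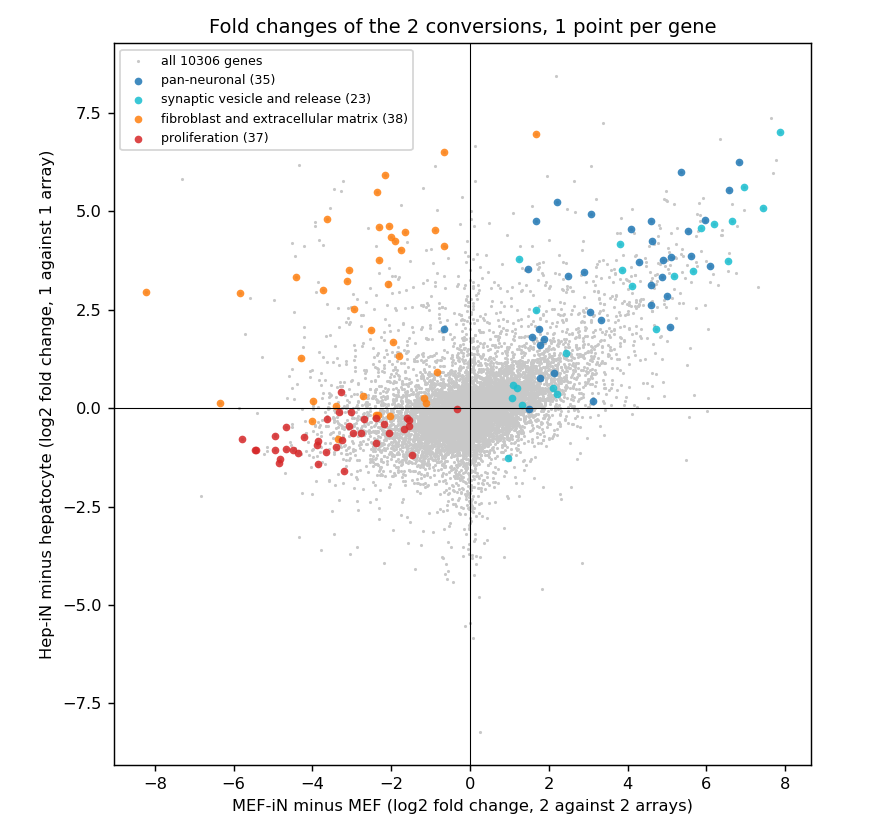
Log2 difference of Hep-iN minus hepatocyte (vertical axis) against MEF-iN minus MEF (horizontal axis), with a point for each of 10306 genes and members of 4 fixed lists in colour. Pan-neuronal genes lie mostly in the upper right, and fibroblast and matrix genes mostly in the upper left, across genes with r = 0.433.

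Between the induced neurons, the Hep-iN array carried hepatocyte and epithelial genes at higher levels than the MEF-iN arrays, and its neuronal genes were lower. This comparison asks what remains of the cell of origin. Lcn2 was at least 256-fold higher on the Hep-iN array, transferrin (Trf) at least 247-fold, Ambp at least 227-fold, transthyretin (Ttr) at least 211-fold, haemopexin (Hpx) at least 201-fold, Saa3 at least 171-fold, Serpina1b at least 156-fold and fetuin A (Ahsg) at least 128-fold. None of these was above background on a MEF-iN array. Of 44 hepatocyte secreted protein genes 39 were 4-fold higher (median 4.81, or 4.06 over 43 members at the bounds). Of 18 hepatocyte transcription factors 9 were 4-fold higher (median 1.98), including Foxa3 (at least 21.6-fold) and Hnf4a (at least 12.6-fold). Of 19 epithelial genes 11 were (median 2.26), including the keratins Krt8 (at least 129-fold) and Krt18 (at least 59.9-fold) and E-cadherin (Cdh1, at least 28.1-fold). Macrophage genes (10 of 15, median 2.48, with Cd14 at least 26.5-fold), smooth muscle genes (6 of 11, median 2.43, with Actg2 at least 25.7-fold) and interferon response genes (10 of 27, median 1.73, with Bst2 at least 21.1-fold) were also 4-fold higher on the Hep-iN array. The matrix gene Timp1 was at least 85.4-fold higher. Hnf4a, Krt8, Cd14, Bst2 and Timp1 were above background on 1 of the 2 MEF-iN arrays. Pan-neuronal genes had a median of -1.31 and synaptic genes of -1.19, with Gap43 at -2.95, Elavl4 at least 4.29-fold lower and Resp18 an exception at 3.28. The 8 largest decreases were adiponectin (Adipoq, at least 32.6-fold lower in Hep-iN), the Hox gene Hoxd10 (at least 19.1-fold), Ogn (-4.87), Ptn (-4.79), the mesenchymal factor Osr2 (at least 13.4-fold), Tfap2b (at least 10.7-fold), Nap1l5 (at least 13.1-fold) and Dctn1 (-4.05). Of 24 Hox genes 9 were 4-fold lower on the Hep-iN array (median -1.19), including Hoxc6 (-3.63) and Hoxa7 (-3.16).

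In total 626 genes were at least 4-fold higher and 170 at least 4-fold lower in Hep-iN than in MEF-iN. The median over all genes was -0.11 here and 0.10 under the authors' scaling alone, which gave 764 higher and 95 lower. The offset of 50 gave 440 genes in place of 796, and the pooled limma fit called 3021. Genes at least 4-fold higher in hepatocytes than in MEF, a list of 608 chosen on arrays outside this comparison, had a median difference of 1.79 between Hep-iN and MEF-iN. Of them 67.4% were over 2-fold higher in Hep-iN, against 14.3% of all genes. The 489 genes at least 4-fold higher in MEF than in hepatocytes had a median of -0.13, which turned to 0.09 under the authors' scaling alone and lay at percentile 72.7 of random lists. Of them 29.0% were over 2-fold lower in Hep-iN, against 11.5% of all genes. Both lists were chosen on arrays of this series and are not independent of it. Across all genes, the difference between Hep-iN and MEF-iN correlated with that between the starting cells at r = 0.406.

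**Figure D3:**
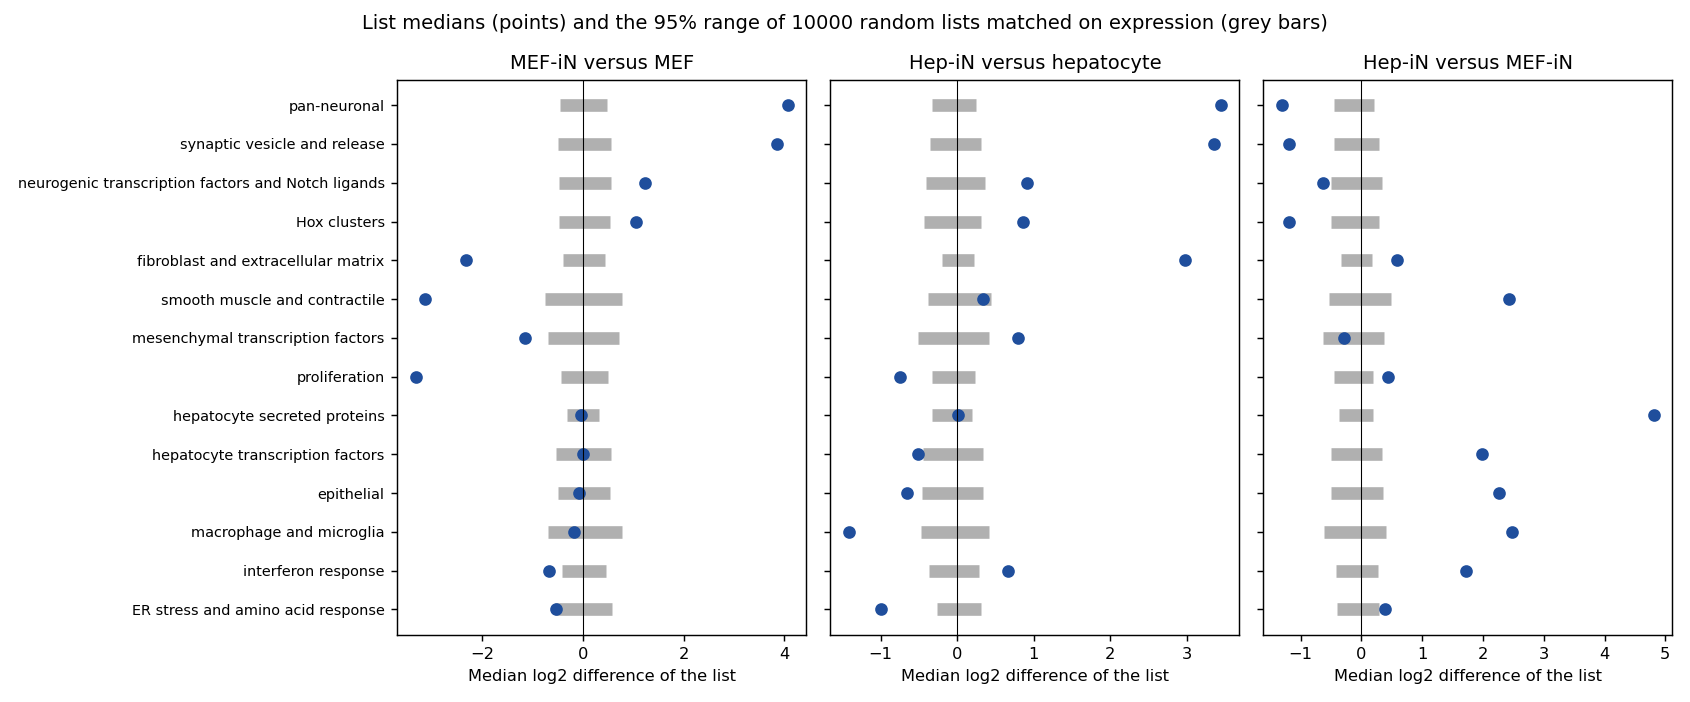
Median log2 difference of fixed gene lists (points, horizontal axis) in 3 comparisons, with grey bars for the central 95% of 10000 random lists. In MEF-iN against MEF the pan-neuronal median is 4.07 and the proliferation median -3.32, in Hep-iN against hepatocytes the pan-neuronal median is 3.44 and the fibroblast and matrix median 2.97, and between Hep-iN and MEF-iN the hepatocyte secreted protein median is 4.81.

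The array labelled cortical neuron was set against each other group as the reference for neurons, and it carried glial genes above all. Against MEF, its 8 largest excesses were the metallothionein Mt3 (at least 243-fold), Plekhb1 (at least 170-fold), the neurotrophin receptor Ntrk2 (at least 147-fold), the sodium pump subunit Atp1b2 (at least 133-fold), the astrocyte water channel Aqp4 (at least 102-fold), the glycolytic enzyme Aldoc (at least 98.1-fold), Cldn10 (at least 89.2-fold) and Gldc (at least 77.3-fold). Of 15 astrocyte genes 13 were 4-fold higher (median 4.98), including Gfap (at least 38.8-fold). Of 11 oligodendrocyte lineage genes 7 were 4-fold higher (median 2.70), including Cldn11 (at least 65.7-fold) and the myelin gene Mag (at least 8.004-fold). Of 35 pan-neuronal genes 8 were 4-fold higher (median 0.81), including Rtn1 (at least 50.8-fold, above background on 1 MEF array) and Scg3 (at least 17.8-fold), and GABAergic genes had a median of 2.13 with the synthesis enzyme Gad1 at least 2.92-fold higher. The 8 largest deficits against MEF were Mgp (-7.80), Lox (-7.56), Actg2 (at least 89.0-fold lower), Timp1 (-7.13), Arhgdib (at least 75.01-fold), Col3a1 (at least 93.9-fold), Col1a2 (-6.82) and Angptl7 (at least 50.9-fold). Against the hepatocyte array, the glutamate transporter Slc1a3 (at least 191-fold), Fxyd6 (at least 136-fold), Igfbp2 (at least 118-fold) and Igfbp5 (at least 117-fold) stood out beside Ntrk2, Atp1b2, Aqp4 and Cldn10. The largest deficits were Serpina1b (at least 288-fold), Ambp (at least 242-fold), Ahsg (at least 233-fold), Afp (at least 201-fold), Serpina1d, Kng1, Hpx and Tm4sf4. There were 708 genes 4-fold higher and 573 lower against MEF, and 729 higher and 704 lower against hepatocytes. Against hepatocytes the larger side depended on the scaling. Median scaling gave 673 higher and 785 lower, and the authors' scaling alone gave 692 higher and 759 lower.

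Induced neurons were above this array in pan-neuronal and synaptic genes and below it in glial and GABAergic genes, and directions drawn from it carry the doubt about its label. In MEF-iN, 21 of 35 pan-neuronal genes were 4-fold higher than on it (median 2.40), including Scg2 (at least 50.9-fold), Elavl2 (at least 67.0-fold) and Chgb (at least 26.0-fold). Of 23 synaptic genes 14 were (median 2.56), including Syt4 (5.95) and Syn1 (5.80). The largest excesses were Dcn (at least 184-fold), Nts (at least 122-fold), Ifi27l2a (at least 87.1-fold), Col3a1 (at least 59.7-fold), Fam155a (at least 57.0-fold) and Vwc2l (at least 49.6-fold). Of 15 astrocyte genes 14 were 4-fold lower in MEF-iN (median -5.14), with Plekhb1 at least 156-fold, Aqp4 at least 93.8-fold, Aldoc at least 90.0-fold, Cyp2d22 at least 87.9-fold, Cldn10 at least 81.9-fold, Gldc at least 70.9-fold, Mmd2 at least 55.9-fold and Pla2g7 at least 55.4-fold lower. GABAergic genes had a median of -1.89, with Gad1 at least 2.68-fold lower. Against Hep-iN the same array had 11 of 35 pan-neuronal genes 4-fold lower (median 1.38 higher in Hep-iN), with Chgb at least 34.9-fold higher in Hep-iN. GABAergic genes had a median of -1.42 in Hep-iN against it, with Gabrb1 at -3.36, Pvalb at -2.59 and Gad1 at least 2.90-fold lower, and Npy an exception at 2.16. Glutamatergic genes had a median of -1.02, which turned to 0.20 over genes detected on at least 2 arrays. Their members went both ways, with Gria2 at 2.10 and Camk2b at 1.85 in Hep-iN and Nrgn at least 1.41-fold lower. In MEF-iN the glutamatergic median was 0.55, with Gria2 and Camk2b also higher than on this array. The cortical factor Fezf2 was at least 5.31-fold lower in Hep-iN. Ambp (at least 273-fold), Hpx (at least 242-fold), Dcn (at least 219-fold), Saa3 (at least 206-fold), Serpina1b (at least 188-fold), Gal (at least 170-fold), Ahsg (at least 154-fold) and Kng1 (at least 145-fold) were highest in Hep-iN relative to it. Slc1a3 (at least 210-fold), Atp1b2 (at least 132-fold), Aqp4 (at least 101-fold), Cldn10 (at least 88.6-fold), Rgcc, Mmd2, Plekhb1 (-6.67) and Ntrk2 (-6.39) were lowest. MEF-iN had 654 genes 4-fold higher and 680 lower than this array, and Hep-iN had 709 higher and 447 lower. Under median scaling MEF-iN had 667 higher and 642 lower, so which side was larger there depended on the scaling. Hep-iN had 835 higher and 358 lower under the authors' scaling alone.

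The genes that set this array apart were also somewhat higher in the induced cells. Of 729 genes 4-fold higher on it than on the hepatocyte array, 37.3% were over 2-fold higher in MEF-iN than in MEF, against 19.6% of all genes, with a median of 0.34. Of 708 genes 4-fold higher on it than in MEF, 31.2% were over 2-fold higher in Hep-iN than in hepatocytes, against 12.5% of all genes, with a median of 0.34. Each median lay above all 10000 random lists. These lists were chosen on an array of this series, hold glial genes, and are not independent evidence of a direction. The medians were 0.73 and 0.59 over genes detected on at least 2 arrays, and 0.23 and 0.16 with the offset of 50.

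The starting cells differed in the genes of their own lineages. On the hepatocyte array against MEF, Trf (at least 439-fold), Lcn2 (at least 266-fold), Serpina1b (at least 261-fold), Ambp (at least 219-fold), Ahsg (at least 211-fold), Ttr (at least 193-fold), alpha-fetoprotein (Afp, at least 182-fold) and Serpina1d (at least 157-fold) were highest. Of 44 hepatocyte secreted protein genes 31 were 4-fold higher (median 4.60, or 6.06 over the 36 members with a value or bound). Mgp (at least 240-fold lower), Col1a2 (at least 121-fold), Ccdc80 (at least 104-fold), Thy1 (at least 93.9-fold), Ptn (at least 77.4-fold), Col3a1 (at least 76.9-fold), Aqp1 (at least 73.3-fold) and Actg2 (at least 72.9-fold) were lowest, and 28 of 38 fibroblast and matrix genes were 4-fold lower (median -4.97). Macrophage genes stood beside the hepatocyte genes: 13 of 15 were 4-fold higher than in MEF (median 4.26), including C1qc (6.28), C1qb (5.26) and Marco (at least 43.9-fold). Proliferation genes had a median of -2.50, with Ccna2 at least 4.999-fold lower. In total 608 genes were 4-fold higher and 489 lower on the hepatocyte array. As in the other comparisons with a lone array, the difference has no replicate check, the offset of 50 lowered the counts by over 1.5 times, and the pooled limma fit raised them. Without the array labelled cortical neuron in the normalization, these counts were 610 and 496.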

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

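Of the tests reported in this part, those of a label swap, of scaling between arrays and of hepatocytes mixed into the Hep-iN sample were chosen only after the result was seen. The second astrocyte and macrophage lists were written before their values were seen.

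A difference between the conversions of fibroblasts and hepatocytes was called for 2401 genes by the interaction test in limma, and for 1138 to 4322 genes when a MEF or MEF-iN array was left out. The hepatocyte conversion has 1 array on each side, whose spread was assumed and not measured, so these calls hold only under that assumption. The interaction also takes in the difference between the starting cells. Fibroblast and matrix genes had median levels of 11.65 and 11.90 in MEF and 6.19 in hepatocytes. In MEF-iN they were 9.48 and 8.67, and in Hep-iN 10.09. Proliferation genes had 9.17 and 9.46 in MEF, 6.65 in hepatocytes, 5.31 and 5.55 in MEF-iN and 5.80 in Hep-iN. Both gaps were widest between the starting cells. No list passed with an estimated correlation (lowest adjusted p = 0.315). Fibroblast and matrix genes had the largest median among the lists, 5.52 (camera adjusted p = 3.33e-26, and adjusted p = 0.485 with an estimated correlation). Col1a1 differed by 6.10 (limma adjusted p = 0.00237). The medians were also above 0 for smooth muscle genes (3.31, camera adjusted p = 9.49e-11), proliferation genes (2.61, camera adjusted p = 2.28e-17) and mesenchymal transcription factors (1.70, camera adjusted p = 1.63e-05). With an estimated correlation their adjusted p was 0.381, 0.315 and 0.381. Neural progenitor genes (1.31, camera adjusted p = 0.00106) and interferon response genes (1.07, camera adjusted p = 5.41e-05) had 0.485 and 0.487 with an estimated correlation. Cholangiocyte and hepatic progenitor genes (1.496, camera adjusted p = 0.0156) and hepatic stellate genes (0.62, camera adjusted p = 0.0177) had 0.535 and 0.524. Synaptic genes (-1.29, camera adjusted p = 0.000262), macrophage genes (-1.19, camera adjusted p = 0.0108) and hepatocyte transcription factors (-0.99, camera adjusted p = 0.0310) had medians below 0, with 0.381, 0.591 and 0.485 for the estimated correlation. Map2 differed by 3.08 (limma adjusted p = 0.00227), and Mapt, the sorting locus, by -1.74 (limma adjusted p = 0.0182). Col1a1, Map2 and Mapt were not above background in hepatocytes, so their sizes depend on the floor of the signal. The size for Map2 also rests on its brightest probe, since its probes differed in MEF-iN against MEF. An estimated correlation rests on 2 residual degrees of freedom, so a list that misses the threshold with it is not argued against.

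Probes without a gene name were left out of the comparisons. Of 900 such probes, 232 rose and 236 fell in MEF-iN against MEF in limma, and 80 of those that rose were above background on both MEF-iN arrays and on no MEF array. The largest rose by 7.02.

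Glial genes were high on the array labelled cortical neuron, such as Aqp4 at 12.16, against 4.26 to 4.41 on the other 6 arrays. A swap of labels with an array of uninfected MEF or hepatocytes is argued against. The MEF-iN pan-neuronal median stood 4.72 above the highest of these arrays, so none of them held a neuronal profile. A swap with a MEF-iN or Hep-iN array was not covered by this test. The astrocyte median stayed 5.58 above MEF with the authors' scaling alone, so the quantile step used here did not make this gap. The authors' own scaling was not removed. A second astrocyte list (26 of 31 genes measured) had a median 4.005 above the highest other array, which glial cells or their RNA in the sample could give. The sort for GFP from the Tau locus was meant to select neurons, but how far it did so is not known here. Mapt, the sorting locus, was lower on this array than on the MEF-iN and Hep-iN arrays. A wrong label or a swap with a sample outside the series would give the same values and stays open, and no biological explanation was tested.

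Hepatocyte genes were high on the Hep-iN array. The secreted protein median stood 5.83 above MEF-iN with the authors' scaling alone, so the quantile step used here did not make this gap. The authors' own scaling was not removed. Of 82 list members above background on the Hep-iN array, 15 were at least 4-fold above the hepatocyte array. The rate between the MEF replicates, taken over all genes, gives 0.191. Among all 10306 genes, not limited to those above background on the Hep-iN array, 560 were, so the shares have unlike bases. For the 15 members, levels above the hepatocyte array argue against mixed-in hepatocytes like those on that array, if it held hepatocytes alone. The hepatocyte array also carried macrophage genes, and no replicate shows how far hepatocyte preparations vary. For the 44 members at or below the hepatocyte array, the SD of the differences was 1.88 times that between replicates, between the bounds set. These members were chosen by the sign of the same differences, which narrows their SD, while the replicate differences were not cut. The ratio therefore cannot decide, and mixing and expression kept by the converted cells cannot be told apart for these members. Members in neither group were not tested. Hepatocytes in another state, which the sort for GFP from the Tau locus together with tdTomato should remove if unconverted, and kept expression in the converted cells stay open for all members.

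Macrophage genes were high on the hepatocyte array, such as Cd163 at 12.38, against 4.16 to 4.67 on the other 6 arrays. The fixed macrophage list was raised on the Hep-iN array too, with a median of 8.51, against 10.83 on the hepatocyte array. It was 6.01 and 6.37 on the MEF arrays, 6.44 and 5.33 on the MEF-iN arrays and 5.86 on the array labelled cortical neuron. The macrophage median stood 4.88 above MEF with the authors' scaling alone, so the quantile step used here did not make this gap. The authors' own scaling was not removed. A second macrophage list (23 of 34 genes measured) had a median 2.79 above MEF, with 17 genes at least 4-fold above, which macrophages or their RNA in the sample could give, although the sort for tdTomato should remove them. The list repeats the pattern on other genes and does not separate this source from others, and no biological explanation was tested.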

How the results depend on the processing

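Tests chosen only after the result was seen are the saddle point fit, the authors' scaling alone, detection at 3 SD and leaving out the array labelled cortical neuron. No paired analysis was possible because replicates are numbered only in the order of deposition. The planned exchange of the table before normalization for the series table was not run, since the series table is the one used. Signal over background limits the folds of genes dim in a group, which are bounds. Unless the alternative's construction shows it (an offset shrinks dim genes, thresholds select, fewer arrays or genes), the cause was not tested. Where a lone array leaves no replicate, 0.226, the mean of the replicates' median differences, stood in for the spread.

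MEF-iN against MEF had 5557 genes past the threshold, 1963 in limma's test against a 2-fold change, 3494 (without MEF-iN replicate 2) to 6355 leaving out an array, 5261 to 5610 under the other alternatives and 5559 without the array labelled cortical neuron. Where a group is left with 1 array, it is assumed to vary like the others. Which direction held more genes in the interaction changed with the scaling and with the array left out. The interaction count was 1138 (without MEF-iN replicate 2), 1303 (without MEF-iN replicate 1), 3940 (without MEF replicate 2) and 4322 (without MEF replicate 1), 1794 to 2522 under the others and 2406 without the array labelled cortical neuron.

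Counts of genes 4-fold apart are given in the order Hep-iN v hepatocyte, neuron v MEF, neuron v hepatocyte, MEF-iN v neuron, Hep-iN v neuron, Hep-iN v MEF-iN, hepatocyte v MEF. With an offset of 50 they were 437, 809, 896, 841, 743, 440 and 714. In the pooled limma fit they were 1566, 4114, 3510, 4402, 3203, 3021 and 2843. At a log2 difference of at least 1 they were 2117, 3388, 3501, 3551, 3301, 2591 and 2531, and at 3 they were 340, 550, 658, 565, 545, 320 and 548. All other alternatives kept these counts within 1.5 times.

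The correlation of the conversions was 0.458 over genes detected on at least 2 arrays, and 0.416 to 0.444 leaving out an array. The median of neuron-high genes in MEF-iN was 0.39 without background correction, 0.23 with an offset of 50, 0.73 over genes detected on at least 2 arrays, 0.37 with the saddle point fit and 0.33 to 0.40 leaving out an array. In Hep-iN it was 0.39, 0.16, 0.59 and 0.36 in the same order, 0.29 with median scaling, 0.28 with the mean of probes, 0.45 with the authors' scaling alone, 0.31 for 8-fold genes and 0.30 to 0.34 leaving out an array. Hepatocyte-high genes between induced neurons had 1.9996 over genes detected on at least 2 arrays, 1.99 with the authors' scaling alone, 2.65 for 8-fold genes and 1.69 to 1.88 leaving out an array. MEF-high genes had 0.0901 with the authors' scaling alone and -0.23 to -0.02 leaving out an array.

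In Hep-iN against the array labelled cortical neuron, the hepatic stellate median turned to -0.0486 with no filter on detection and the glutamatergic median to 0.20 over genes detected on at least 2 arrays. Map2 lost its call with the mean of probes (limma adjusted p = 0.347) and Col1a1 without MEF-iN replicate 2 (limma adjusted p = 0.0610). The camera calls of voltage-gated channels, interferon response and the delivered factors were each lost under some alternatives, and Hox, cholangiocyte, glutamatergic, ER stress and macrophage lists gained calls under some. Over all alternatives 408 camera results kept their side of the threshold, 17 became stronger and 9 weaker, and 292 results of named genes kept theirs, with 2 weaker. Of the other values, 3686 stayed within the spread and 1617 moved. The median of all genes in Hep-iN v MEF-iN was -0.11, -0.13 with median scaling and 0.10 with the authors' scaling alone. It was 0.14 in Hep-iN v neuron with the authors' scaling alone, and -0.15 in Hep-iN v hepatocyte with median scaling.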

Other observations

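The test reported in this part was written before its values were seen, on a pattern noticed in these data.

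The lists in this paragraph were not called by camera, members went both ways, and 5557 of all 10306 genes passed, so members are given as values only. In MEF-iN against MEF, 6 of 12 skeletal muscle genes rose in limma, led by the myosin light chain Myl1 (at least 12.4-fold) and the troponin Tnnc1 (2.49), while 2 fell and 4 did not pass (median 0.74, camera adjusted p = 0.144). Reln, a member of the hepatic stellate list, rose at least 20.5-fold in MEF-iN, where that list's median was -0.05 (0.00412 with median scaling). It was at least 15.0-fold higher in Hep-iN than in hepatocytes, where the list's median was 1.33. Of 21 glycolysis and hypoxia genes 7 fell, including Hk2 (-3.44) and Adm (-3.36), and 2 rose. Of 11 regulators of splicing and of repression of neuronal genes 4 fell, among them Ptbp1 (-1.62), and 3 rose. This list mixes non-neuronal regulators with splicing factors of neurons, such as Rbfox1 (2.55), so it has no single direction to look for. Of 20 ER stress and amino acid response genes 10 fell, including Phgdh (-2.88) and Creld2 (-2.33), and 2 rose, or 11 and 2 adjusted over the list alone. In Hep-iN against hepatocytes, Hoxa5 (at least 5.14-fold) and Hoxb5 (at least 4.16-fold) were higher, and Npy, a neuropeptide gene, was at least 6.76-fold higher.

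Fkbp5, Sgk1, Klf9 and Pdk4, genes induced by glucocorticoids, were lower after both conversions. Sgk1 fell by 4.01 and Klf9 fell by 2.55 in MEF-iN against MEF, where the probes of Fkbp5 and Pdk4 were not above background in MEF-iN. In Hep-iN against hepatocytes the log2 differences of Fkbp5, Sgk1, Klf9 and Pdk4 were -3.70, -2.17, -2.38 and -3.52. They were chosen after their values were seen. A hypothesis is that the induced cells' medium may have held less glucocorticoid than that of the starting cells. A second list of such genes (21 of 25 measured) had medians of -0.61 in MEF-iN against MEF and -0.80 in Hep-iN against hepatocytes, between the bounds of -1 and -0.5 set for it, so the test left the hypothesis open. Members went both ways in MEF-iN against MEF, where 9 fell, 3 rose and 9 did not pass. Those that fell include Errfi1 (-3.24, limma adjusted p = 3.38e-05), Angptl4 (-2.29, limma adjusted p = 0.000600) and Tgm2, whose probe was not above background in MEF-iN. Tsc22d3 (1.86, limma adjusted p = 0.000882), Lpin1 (1.85, limma adjusted p = 0.000611) and Per1 (0.66, limma adjusted p = 0.0317) rose. These 6 genes were named after their values were seen. The composition of the media was not used here.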
